A study of Mus musculus with 6 samples.

How the data were processed

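Total RNA from mouse SNpc was sequenced after preparation with Illumina protocols, per the labels' protocols. The 4 captured samples are midbrain dopaminergic neurons stained for tyrosine hydroxylase and taken by laser capture, and the 2 punched samples are 1 mm punches of frozen slices 2 mm thick. En2 was injected as recombinant protein made in bacteria (300 ng at 4 µM in 2 µl, with 3 µg of colominic acid) 30 min after 6-OHDA, against a saline vehicle, per the labels. How many animals stand behind each sample is not given in the sources used here. The labels name the infused protein En2, while the deposited tables of that pair carry En1 in their names and headers. The labels were followed.

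The submitters' processing notes name Bowtie, HTSeq, DESeq 1.8.3 and the build mm10, with neither roles nor further versions. A column header of the punched pair's comparison table names mm9. The files hold no coordinates, and gene positions here come from GENCODE M21 on GRCm38. For the captured samples the authors deposited read counts per transcript (95533 transcripts of 35049 genes), in which a read can count for every transcript it overlaps. For the punched samples the authors deposited counts per gene (37991 genes). The authors' deposited comparison tables give log2 fold changes for the captured pairs, a linear fold change (ratio) for the punched pair, and p-values with adjusted p-values made without replicates. The 6 mean columns per library in those tables were not used here. Symbols came from a table of gene identifiers that held 33725 of the captured and 32919 of the punched genes, and otherwise from the files. Among captured transcripts, 9402 carry no gene identifier and were left out, with 2.93% to 4.78% of the counts. Of the alignments processed for the punches, 42.6% and 39.6% were not aligned and 16.4% and 16.9% lay in no feature; these stay out of the counts.

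In the punched files 4 counts stand 1 column to the right of the others, and they were moved back. One of them is Birc3, with 1575 reads after 6-OHDA then En2. The fold change in the authors' deposited table implies 169 reads for this gene. With 1575 the counts sum to 19044672, which equals the alignments processed minus the categories that HTSeq set aside, and with 169 they sum to 19043266. The 1575 reads were kept. Of 20085 genes with reads after 6-OHDA, the counts after 6-OHDA then En2 differed by more than 0.5 reads from those the fold changes imply for 1 gene, Birc3. Apart from Birc3, the authors' log2 fold changes differ from the log2 ratio of the raw counts by 1 offset per table (-1.00, -0.14 and -0.23), within a tolerance of 0.01.

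Each captured gene was represented by the transcript with the most reads over the 4 captured libraries, a choice made after the file format and before any ratio had been seen. Counts of a pair were scaled by the median of ratios over genes with reads in both, 0.5 was added, and the log2 ratio of the second library over the first was taken, with an exact 95% counting interval from the Clopper-Pearson interval of a library's share of the gene's reads. The rule of size asks for at least 20 reads in 1 of the 2 libraries, a log2 ratio of at least 1 in size and an interval that excludes 0. A gene with 0 reads in a library is given as at least a number of times higher or lower, against a floor of 3 reads there, a one-sided limit that lies nearer to 0 reads than the end of the 2-sided interval. With 1 sample per group nothing was tested for significance. Of each gene list, the median log2 ratio was set among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression, as a description of these libraries. The 28 lists (677 genes of cell types and pathways), the groups, the rule of size, the alternatives and the rule for naming genes were fixed before the data were examined. That rule takes per comparison En1, En2, Th, Slc6a3, Ndufs1, Ndufs3 and Map1b, the 12 genes per direction with the largest conservative bound (the interval's end nearest 0), and up to 2 members of each list with the highest and 2 with the lowest ratio. Between the En1+/- and infusion comparisons it takes up to 10 genes past the rule in opposite directions. Genes without a proper symbol and mitochondrial and ribosomal RNA genes were left out of the 12. Not every gene that the rule takes is reported here. A further 6 lists were written after the leading genes had been seen and hold some of them.

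The steps were tested on simulated counts with 200 changed genes per pair. Of 100 genes changed by a log2 ratio of 1.5, 98.0% were recovered in the En1+/- pair, 100.0% in the infusion pair and 100.0% in the punched pair. Of 100 changed by 3, 100.0% were recovered in each. Counting intervals covered the true ratio in 96.1%, 96.0% and 95.2% of measured genes. Among unchanged genes 72, 63 and 34 passed the rule. The simulation holds counting error only. Alternatives were library totals, TMM, no minimum count and a minimum of 100 reads, other thresholds and intervals, the authors' fold changes, scaling without mitochondrial and ribosomal RNA genes, 10 expression bins, and lists without their highest and lowest gene. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, and edgeR 4.0.16 in R 4.3.3 for TMM factors. Near-identical paralogs (protocadherins, zinc finger genes, schlafens, histocompatibility genes) and overlapping or antisense genes can share reads, and whether counting used strand is not given in the sources used here. Their values are uncertain for that reason.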

Results

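RNA was sequenced from the substantia nigra pars compacta (SNpc) of mice, the midbrain region that holds the dopaminergic neurons projecting to the striatum. The 6 samples formed 6 groups of 1 sample each and 3 pairs. The first pair set En1+/- mice, which carry 1 working copy of the homeobox gene Engrailed 1, against wild type mice at 6 weeks. The second set the side of the brain that had received Engrailed 2 protein (En2) from an osmotic pump for 7 days against the opposite side, at 8 weeks. In both, neurons stained for tyrosine hydroxylase had been cut out by laser capture. The third pair used tissue punches from mice injected with 6-hydroxydopamine (6-OHDA), a toxin taken up by dopaminergic neurons. After 30 min these mice received En2 with colominic acid or a saline vehicle.

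Counts over transcripts summed to 16145262 in the wild type library, 21332308 in the En1+/- library, 18081543 on the contralateral side and 16330774 on the infused side. Mitochondrial ribosomal RNA took 74.4% of the wild type counts, 58.5% of the En1+/- counts, 71.6% on the contralateral side and 62.4% on the infused side. The 95% Wilson intervals of these shares, in the same order, were 74.4 to 74.4, 58.4 to 58.5, 71.6 to 71.7 and 62.4 to 62.4. Outside mitochondrial and ribosomal RNA genes, the most-read transcripts of these libraries held 1510195, 3272422, 1908530 and 2308718 counts in the same order. The punched libraries held 15927206 counts over genes for 6-OHDA and 19044672 for 6-OHDA then En2. With 1 sample per group no difference below has a replicate check, and no test of significance was made. Intervals in parentheses are exact 95% counting intervals. They cover counting error in these libraries only, since reads are not independent molecules.

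The shares of reads taken by cell type genes were set out for the captured and the punched samples. Genes of the dopaminergic list took 12169 CPM (reads scaled to a common total outside mitochondrial and ribosomal RNA genes) in wild type, 11411 in En1+/-, 12500 on the contralateral side and 13740 on the infused side. In the punches they took 898 after 6-OHDA and 1113 after 6-OHDA then En2. Oligodendrocyte genes took 30975 CPM in wild type, 25919 in En1+/-, 20899 on the contralateral side and 21656 on the infused side, and 33061 after 6-OHDA and 26128 after 6-OHDA then En2 in the punches. In each captured library oligodendrocyte genes thus took more reads than dopaminergic genes. The captured libraries hold RNA of other cells too, and their ratios cannot be assigned to dopaminergic neurons alone. Captured files count transcripts and punched files count genes, so no ratio was formed between them. Both punched samples had received 6-OHDA, so collection and lesion cannot be told apart in their dopaminergic values.

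**Figure D1:**
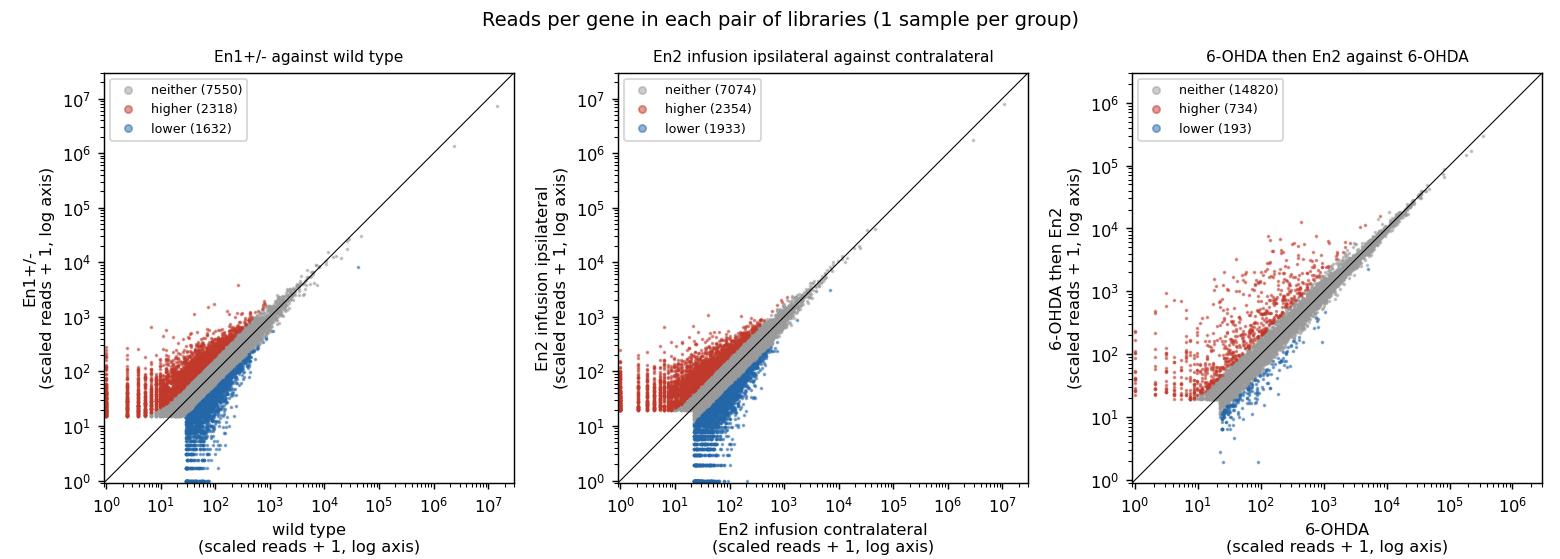
Scaled reads per gene plus 1 in the first library (horizontal, log axis) against the second (vertical, log axis) of each pair, 1 sample per group. Red and blue points pass the rule of size as higher or lower. The captured pairs scatter widely at low reads, with 2318 and 2354 genes higher, while the punched pair lies close to the diagonal apart from 734 genes higher and 193 lower.

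The first comparison asked which transcripts differ in the captured nigral tissue of mice that lack 1 copy of En1. En1 itself (ENSMUSG00000058665; GRCm38 chromosome 1, 120602418 to 120607992) was 3.28-fold lower in En1+/-, with 77 reads in wild type and 47 in En1+/- (109 and 33.2 after scaling), a log2 ratio of -1.70 (-2.27 to -1.17). The paralog En2 (chromosome 5, 28165694 to 28172166) had a log2 ratio of 0.20 (-0.58 to 1.04). For genes of dopamine synthesis and uptake the ratio was -0.15 (-0.25 to -0.05) for Th, which encodes tyrosine hydroxylase, and 0.02 (-0.03 to 0.08) for Slc6a3, the dopamine transporter gene. The complex I gene Ndufs1 had a ratio of 0.07 (-0.21 to 0.35) and Map1b, which encodes a microtubule-associated protein, 0.01 (-0.03 to 0.05). Ndufs3 had 2 reads and 0 reads, too few for a ratio.

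By the rule of size, 2318 of 11500 measured genes were higher in En1+/- and 1632 were lower. The same rule passed 2958 of 10742 genes for the contralateral side against wild type, which differ in age and treatment but not in En1 genotype. Scaling the En1+/- pair by library totals, which mitochondrial ribosomal RNA dominates, moved the median log2 ratio of all measured genes up by 0.78. It gave 5139 higher and 756 lower, a share of 87.2% higher among genes past the rule against 58.7%. With at least 20 reads in both libraries, a setting chosen after seeing the data, 985 were higher and 1005 lower (49.5% higher), and with no minimum count 2537 were higher and 2841 lower (47.2% higher). Every ratio in this pair is relative to the median gene, and that of Th turned to 0.63 under library totals. Of the genes past the rule, 177 higher ones had 0 reads in wild type and 68 lower ones had 0 reads in En1+/-. The minimum of 20 reads applied to unscaled counts, and the En1+/- library was deeper (3272422 against 1510195 reads outside mitochondrial and ribosomal RNA genes). A higher gene could thus enter at fewer scaled reads than a lower one, so the directions were not counted alike. For genes with 0 reads in a library, folds given as at least are against a floor of 3 reads there, which differs from the interval's end by which genes were ranked. Among the leading genes, Wnk4, which encodes a kinase that regulates ion transport, had 0 and 395 reads and was at least 65.8-fold higher. Zfp74 was at least 57.5-fold higher and Cyb5r4 at least 50.7-fold higher, while Zfp111 had 4 and 926 reads and a log2 ratio of 6.73 (5.49 to 8.73). Among lower genes, Nsun6, an RNA methyltransferase gene, had 53 and 0 reads and was at least 35.3-fold lower, Elovl3 and Gadl1 were each at least 30.7-fold lower, and Tdp1, which acts in repair of DNA breaks, was at least 25.3-fold lower.

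Of 28 gene lists, 2 had a median outside the central 95% of random lists matched on expression, where 1.40 would be expected by chance. The mitochondrially encoded list had a median of -0.71 (percentile 0), with mt-Rnr2 at -0.97, and none of its 9 measured genes passed the rule. The oligodendrocyte list had a median of -0.20 (percentile 1.92), with 2 of 15 genes lower: Cldn11 at -1.04 and Opalin at -2.05. It lay inside the central 95% with 10 bins of expression and without its highest and lowest gene. Under library totals both medians turned positive, as did those given below for the p53 and complex I lists. In the dopaminergic list 5 of 24 measured genes were higher and 1 lower, with a median of 0.32 (percentile 94.2). Markers of other cell types went both ways, with medians of -0.01 for the glutamatergic and 0.18 for the astrocyte list beside the oligodendrocyte value above. In the GABAergic list 3 of 11 genes were higher and 1 lower (median 0.58, percentile 95.3), with Tal1 14.6-fold higher (9.71 to 22.9). In the oligodendrocyte precursor list 3 of 8 were higher and 1 lower (median 0.48, percentile 87.5), with Pdgfra 3.59-fold higher (2.91 to 4.47) and Bmp4 at least 15.8-fold higher on 0 and 95 reads. In the endothelial and mural list 4 of 12 were higher and 1 lower (median 0.54, percentile 92.0). Among dopaminergic genes, Otx2, a midbrain transcription factor gene, was 14.2-fold higher (9.51 to 22.0) and Aldh1a7 was 4.79-fold higher (3.42 to 6.88), whereas Drd2, the autoreceptor for dopamine, was 2.27-fold lower at a log2 ratio of -1.18 (-1.38 to -0.98). The DNA damage and p53 list held 7 higher and 4 lower genes among 27, with Xpc at 4.49 (3.23 to 6.50), Aen at 4.52 (2.85 to 7.81) on 2 and 107 reads, and Gadd45b at -3.46 (-6.13 to -1.98) on 20 and 3 reads. Its median was -0.18 (percentile 11.9). In the DNA repair list 6 of 33 genes were higher and 4 lower (median 0.40, percentile 89.4). In the chromatin regulator list 12 of 58 were higher and 10 lower (median 0.26, percentile 83.7). Over all measured genes of this pair 20.2% were higher and 14.2% lower. Mitochondrial complex I had a median of -0.15 (percentile 6.63) with 3 of 34 genes lower, among them Ndufv2 at -1.38. The cytokine, complement and interferon list had 4 higher and 2 lower genes among 11 (median 0.86, percentile 94.8), including Irf9 at 4.26 (2.84 to 6.71) on 3 and 128 reads. In the authors' deposited table, 60 transcripts were higher and 1 was lower at an adjusted p under 0.05, and En1 had an adjusted p of 1 there.

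**Figure D2:**
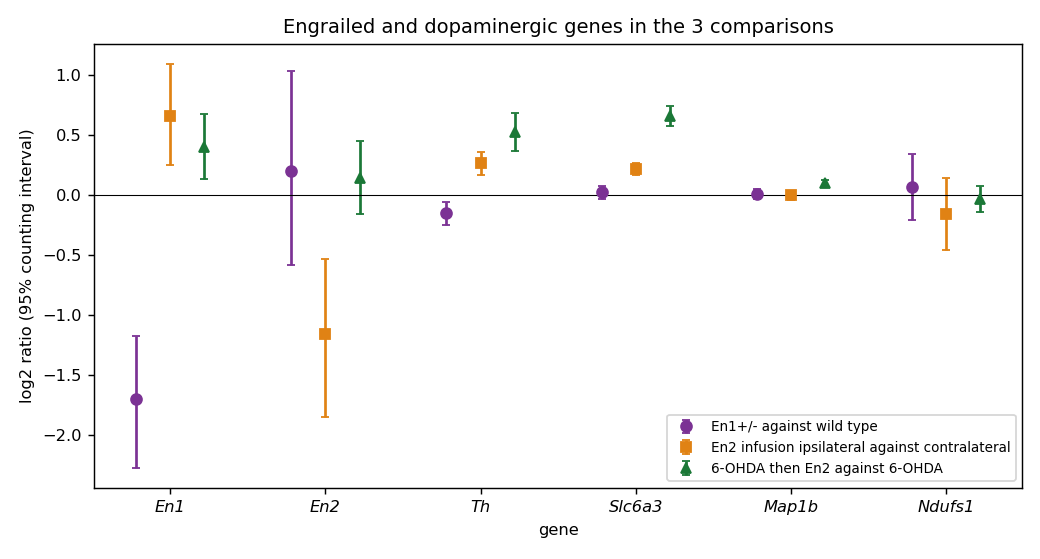
Log2 ratios of En1, En2, Th, Slc6a3, Map1b and Ndufs1 in the 3 comparisons, with exact 95% counting intervals as bars and 1 sample per group. En1 lies at -1.70 in En1+/- against wild type, En2 at -1.16 on the infused side, and Th and Slc6a3 at 0.53 and 0.66 in 6-OHDA then En2 against 6-OHDA.

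The second comparison asked how transcripts differ with infused En2 protein in the captured tissue of the same region. Genes of reactive astrocytes, microglia and immune signalling included many that were higher on the infused side. Serpina3n, a protease inhibitor gene of reactive astrocytes, was 27.3-fold higher (19.7 to 38.9), and Gfap, the intermediate filament gene of astrocytes, was 6.25-fold higher (5.28 to 7.45). The lysosomal membrane gene Laptm5 of microglia was 5.72-fold higher (4.35 to 7.64), and C5ar1, a complement receptor gene, had 0 and 109 reads and was at least 32.2-fold higher. In the cytokine, complement and interferon list 17 of 20 measured genes were higher and none lower, with a median of 2.03 (percentile 100). C1s1 was at least 16.6-fold higher and Il1b at least 8.87-fold higher. In the microglia and macrophage list 11 of 18 genes were higher and none lower (median 1.45, percentile 100). Its lowest members, Tmem119 and P2ry12, which mark resting microglia, had ratios of -0.08 and -0.38, both positive under library totals. In a homeostatic microglia list written after the leading genes had been seen, 3 of 11 genes were higher and none lower (median 0.26), among them Selplg, 8.71-fold higher (5.20 to 15.6). In the reactive astrocyte list 5 of 8 genes were higher and 1, Tm4sf1, was lower (median 1.67, percentile 99.6). The astrocyte list itself had a median of -0.04 (percentile 23.4) with Gfap as its 1 higher gene and 1 lower gene, and this median turned positive under library totals.

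The dopaminergic list had a median of 0.34 (percentile 96.4) with 3 of 22 genes higher and none lower. Ddc, which makes dopamine from its precursor, was 2.37-fold higher (2.19 to 2.57), and the neurotensin receptor gene Ntsr1 was 2.20-fold higher (1.92 to 2.52). Th had a log2 ratio of 0.27 (0.17 to 0.36) and Slc6a3 of 0.22 (0.17 to 0.27). The pan-neuronal list had a median of -0.28 (percentile 1.53) with the neurofilament gene Nefm at -1.31, and this median turned positive under library totals. En2 transcripts were 2.25-fold lower on the infused side (62 and 31 reads, log2 ratio -1.16, interval -1.84 to -0.53), and En1 had a ratio of 0.66 (0.25 to 1.09). Ndufs1 had a ratio of -0.16 (-0.46 to 0.14), which turned positive under library totals. Ndufs3 had 1 and 23 reads, a log2 ratio of 3.83 with an interval of 1.73 to 9.72. Map1b stood at 0.999 times the contralateral level (0.973 to 1.03). In the complex I list 5 of 34 genes were higher and 1 lower, with a median of 0.08 (percentile 42.5). Immediate early genes went both ways, with Egr1 at -5.78 (-11.70 to -3.86) on 74 and 1 reads and Nr4a1 103-fold higher (18.1 to 4100.3) on 1 and 116 reads. Mitochondrially encoded genes had a median of -0.38 (percentile 0.1) that turned positive under library totals. The heat shock list had a median of -0.44 (percentile 2.78).

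Over all genes 2354 of 11361 were higher and 1933 lower, beside the 2958 of 10742 past the rule for the contralateral side against wild type. Library totals moved the median of all measured genes up by 0.42 and gave 3594 higher and 1280 lower, a share of 73.7% higher among genes past the rule against 54.9%. With no minimum count 2827 were higher and 3099 lower (47.7% higher). Of the 28 lists, 5 had a median outside the central 95% of random lists, where 1.40 would be expected by chance. The leading higher genes were Tmem121, with 0 and 258 reads and at least 76.3-fold higher against the floor of 3 reads, Six4, at least 48.5-fold higher, and Ccn2, a matricellular growth factor gene, at least 45.6-fold higher. Among lower genes Srrm4os had 199 and 0 reads and was at least 74.8-fold lower, Xkrx was at least 33.4-fold lower, and Ndufaf2, an assembly factor gene of complex I, was at least 27.8-fold lower. Srrm4os is annotated antisense to another gene, and strand was not given for the counting, so its reads cannot be assigned to 1 strand. The authors' deposited comparison lists 46 transcripts as higher and 2 as lower at an adjusted p under 0.05 in its table.

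**Figure D3:**
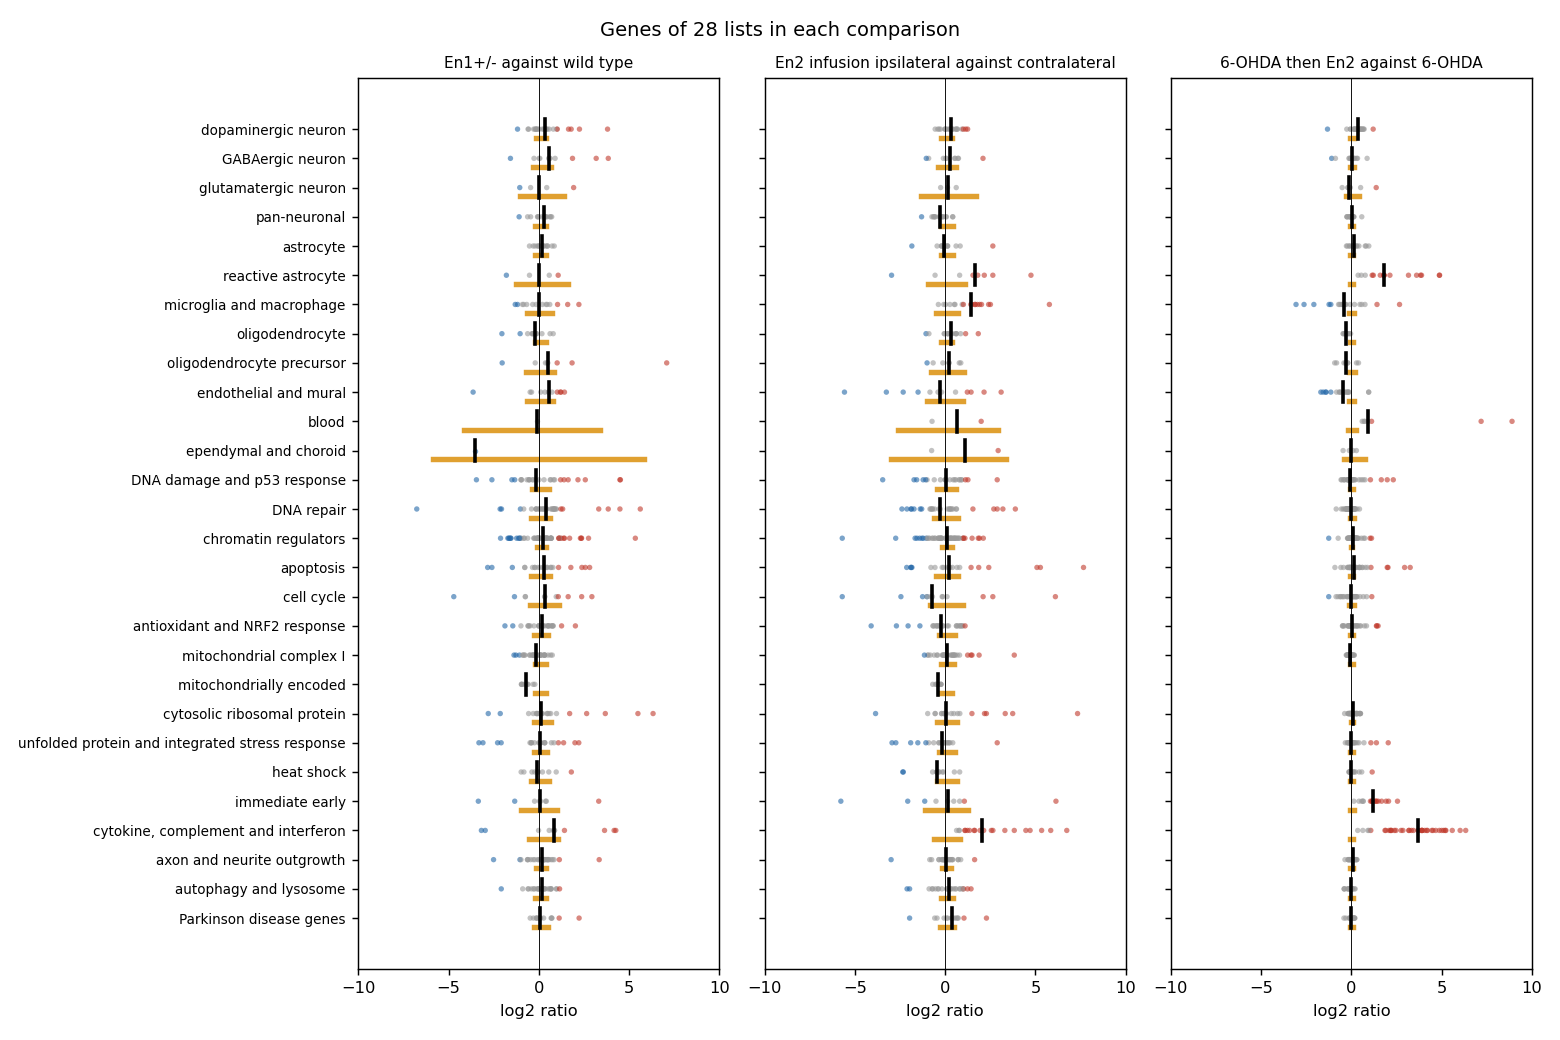
Log2 ratios of the measured genes of 28 lists (points; red higher, blue lower and grey neither by the rule of size), the median of each list (black line) and the central 95% of medians of 10000 random lists matched on expression (orange bar) in the 3 comparisons. The cytokine, complement and interferon list has medians of 2.03 on the infused side and 3.69 in 6-OHDA then En2 against 6-OHDA.

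The third comparison asked what En2 protein given after 6-OHDA changes in nigral tissue. Interferon and cytokine genes were far higher in the library that had received En2. Rsad2, an antiviral gene that interferon induces, had 119 and 8359 reads and was 59.7-fold higher (49.9 to 72.2). The interleukin gene Il1b was 81.8-fold higher (54.4 to 129), the chemokine gene Ccl5 66.5-fold (41.4 to 114) and Cxcl10 29.2-fold (26.4 to 32.3). In the cytokine, complement and interferon list 35 of 39 measured genes were higher and none lower, with a median of 3.69 (percentile 100). The largest bounds among all genes were also those of immune genes. Slfn4 had 2 and 1022 reads and a log2 ratio of 8.47 (6.91 to 11.81), and Csf3, which encodes granulocyte colony-stimulating factor, had 1 and 537 reads and a ratio of 8.29 (6.35 to 14.14). S100a8, a calcium-binding protein gene abundant in neutrophils, had 0 and 257 reads and was at least 72.9-fold higher, and its partner S100a9 was 162-fold higher (62.9 to 595).

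Reactive astrocyte genes were higher with them, 13 of 16 and none lower (median 1.804, percentile 100), among them Timp1, 30.5-fold higher (17.3 to 59.6). The general astrocyte list had a median of 0.16 (percentile 99.985) with no gene of 15 past the rule. Immediate early genes were higher too, 12 of 17 with none lower (median 1.16, percentile 100), with Egr2 at 2.55 (2.06 to 3.10) and Junb at 2.05 (1.74 to 2.39). Microglial genes split. Tmem119 was 8.57-fold lower (log2 ratio -3.07, interval -3.78 to -2.48), the fractalkine receptor gene Cx3cr1 6.20-fold lower (-2.63, -2.88 to -2.39) and P2ry12 4.26-fold lower, whereas Cd14, a receptor for bacterial lipopolysaccharide, was 6.33-fold higher (5.82 to 6.89). The whole microglia list had 2 higher and 5 lower genes among 20 (median -0.44, percentile 0). Endothelial and mural genes included 5 lower and no higher among 18 (median -0.48, percentile 0), with Slco1a4 at -1.57 and Abcc9 at -1.70. The oligodendrocyte list had a median of -0.31 and the oligodendrocyte precursor list one of -0.32 (both percentile 0), with no gene past the rule in either.

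Dopaminergic genes were a little higher as a group, with a median of 0.34 (percentile 100), although 1 of 24 passed the rule in each direction, Lmx1a at 1.20 and Foxa2 at -1.33. Slc6a3 had 1820 and 3382 reads, a log2 ratio of 0.66 (0.58 to 0.74), and Th had 519 and 880 reads, a ratio of 0.53 (0.37 to 0.69). Both lie under the rule of size. In the authors' deposited table the adjusted p was 0.0360 for Slc6a3 and 0.961 for Th. En1 had a ratio of 0.40 (0.13 to 0.67), En2 of 0.15 (-0.15 to 0.45), Ndufs1 of -0.03 (-0.14 to 0.08), Ndufs3 of -0.15 (-0.34 to 0.04) and Map1b of 0.10 (0.08 to 0.12). The pan-neuronal median was 0.01 (percentile 65.9), negative under library totals, and that of complex I was -0.08 (percentile 0.85) with no gene past the rule. Among apoptosis genes 5 of 36 were higher, including the inflammatory caspase gene Casp4, 9.65-fold higher (6.71 to 14.3), and Birc3 with 174 and 1575 reads, 7.70-fold higher (6.58 to 9.06). The authors' deposited table gives Birc3 a log2 fold change of -0.28, which does not match these counts. Among antioxidant genes 3 of 33 were higher, including the metallothionein genes Mt1 at 1.40 and Mt2 at 1.48. Over all genes 734 of 15747 were higher and 193 lower. The authors' deposited table listed 465 genes higher and 39 lower at an adjusted p under 0.05. Of the 27 lists with measured genes, 16 lay outside the central 95% of random lists, where 1.35 would be expected. The random lists vary little in this pair, so medians as small as 0.06 fell outside. The mitochondrially encoded genes are listed at 0 in both punched libraries.

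Across genes, the ratios of the 3 comparisons were set against each other. Over 10077 genes measured in both captured pairs, Spearman's correlation was 0.00465 and Pearson's 0.0274. Spearman's correlation was 0.0121 and Pearson's 0.0292 between En1+/- and 6-OHDA then En2 over 10846 genes, and they were 0.0295 and 0.112 between En2 infusion and 6-OHDA then En2 over 10639 genes. Genes are not independent replicates, and no library was shared between pairs. Genes higher in both En2 comparisons numbered 107, where independent lists would share 40.4, and those lower in both numbered 11 against 9.54. Those higher on the infused side and lower after 6-OHDA then En2 numbered 23 against 11.03, and the reverse 37 against 35.0. Between En1+/- and 6-OHDA then En2, which share no En2 treatment, 67 genes were higher in both against 31.5 and 12 lower in both against 10.1, 33 were higher in En1+/- and lower in the other against 13.4, and 26 were the reverse against 23.7. Between En1+/- and En2 infusion, 387 genes were higher in both against 271.6 for independent lists, 288 were lower in both against 224.3, 354 were higher in En1+/- and lower on the infused side against 266.9, and 295 were the reverse against 228.3. All 4 overlaps thus lay above the independent value. Of the genes past the rule in opposite directions, Adamts17 had the largest smaller bound, with 24 and 0 reads in wild type and En1+/- and 0 and 54 reads on the contralateral and infused sides. Hes6 had 20 and 0 reads in the first pair and 5 and 142 in the second, and Rai1 had 14 and 309 in the first and 85 and 8 in the second.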

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

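Reads lay outside the gene counts in all 6 libraries, and what they hold was not analysed. Transcripts with no gene identifier held 2.93% of the counts in wild type, 4.78% in En1+/-, 3.44% on the contralateral side and 4.67% on the infused side. In the punched libraries 16.4% of alignments after 6-OHDA and 16.9% after 6-OHDA then En2 lay in no feature. No group had the 4 samples that a search for samples far from the others needs.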

How the results depend on the processing

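No paired analysis was possible because each group has 1 sample and no value comes from a test; leaving out replicates and other splits of the samples could not be run for the same reason. Depth limits which genes count: a gene under 20 reads in both libraries of a pair was not measured. At least 20 reads in both libraries, and sums over transcripts, were chosen after seeing the data. The cause of a moved value was not tested, except that stricter thresholds and minimums pass fewer genes by construction and looser ones more. For En1+/- against wild type, the main counts of 2318 higher and 1632 lower became 5139 and 756 under library totals, 1266 and 310 with at least 100 reads, 962 and 617 at a log2 ratio of 2, 1211 and 857 with the whole interval beyond 1, and 985 and 1005 with 20 reads in both libraries. Lower genes numbered 2841 with no minimum count and 2535 at a 1.5-fold ratio. For En2 infusion, 2354 and 1933 became 3594 and 1280 under library totals, 1001 and 470 with at least 100 reads, 1016 and 800 at a log2 ratio of 2, 1340 and 1012 with the whole interval beyond 1, and 1125 and 846 with 20 reads in both. Lower genes numbered 3099 with no minimum count. For 6-OHDA then En2, 734 and 193 became 484 and 58 with at least 100 reads, 1157 and 457 at a 1.5-fold ratio, 348 and 27 at a log2 ratio of 2, 484 and 61 with the whole interval beyond 1, and 460 and 104 with 20 reads in both. Lower genes numbered 296 with no minimum count. TMM, the 99% interval, the authors' fold changes and scaling without mitochondrial and ribosomal RNA genes kept each count within 1.5 times the main one. Sums over transcripts, run for the captured pairs only, did so there. Under library totals the median log2 ratio turned to 0.58 for oligodendrocyte and 0.072 for mitochondrially encoded genes in En1+/-, and to 0.14 for pan-neuronal and 0.040 for mitochondrially encoded genes with En2 infusion. That setting shifts all genes of a pair by 1 factor. In En1+/- the lists outside the central 95% of random lists fell from 2 to 1 with 10 bins of expression and to 1 without each list's highest and lowest gene, in both cases through the oligodendrocyte list. Spearman's correlation between En1+/- and En2 infusion was 0.0745 with at least 100 reads. No named gene past the rule of size changed sign under library totals, TMM or the other minimums of reads. That outcome was fixed: the minimums leave each ratio as it is, and each factor shifted ratios by less than the rule of size. Across these settings 102 log2 ratios of named genes moved outside their counting interval, 100 of them under library totals. Another 1324 stayed inside, among them all those under the other minimums of reads, which could not move. The side of the central 95% on which a list lay was kept in 480 cases, lost in 6 and gained in 4. Library totals and TMM shift a list and its random lists almost alike. All cases under them were kept and say little about stability.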

Other observations

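Of the tests here, those on lymphocytes or red cells, neutrophils, bacterial components, microglia number, dopaminergic neurons and both scalings were chosen only after the result was seen, as were their spread limits and the windows matched on gene number; those on captured molecules, read depth, Engrailed dose and the region around En1 were set before. The 6 lists used in this part were written after the leading genes had been seen and hold some of them, so their values describe the same data again. In 6-OHDA then En2 against 6-OHDA, the homeostatic microglia list had 7 lower and no higher genes among 12, with a median of -1.69, including Tmem119 at -3.07 and Gpr34 at -2.88. Activated microglia and macrophage genes had 3 higher and none lower among 13 (median 0.47). Neutrophil genes had 8 of 8 measured members higher (median 7.14, or 5.40 with genes at 0 reads set at their bound), and endotoxin-induced genes 16 of 16 (median 4.14). On the infused side, 6 of 10 activated microglia genes were higher and 1 lower (median 4.31, or 3.12 at the bounds). Of the 17 listed genes 4 had at least 20 reads on the contralateral side, so most measured members entered through their reads on the infused side, and Ms4a7 had 0 and 89 reads. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had reads in all 6 libraries. Their list had a median of -0.99 in En1+/- against wild type (percentile 1.8 of random lists, 2 of 4 measured genes lower, with Ddx3y at -1.42) and of -0.69 on the infused side (percentile 4.44, 1 of 4 lower). Xist had 34 and 4 reads in the punches.

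Immune genes were higher after 6-OHDA then En2. A difference in scaling shifts every gene of a pair alike and is argued against, since the median of the cytokine, complement and interferon list lay 3.61 above the upper end of the central 95% of random lists. Lymphocyte and red cell genes had a median of 0.83 over 6 measured genes with an upper quartile of 1.06 (9 of 18 listed genes also stand in a fixed list), which leaves a contribution of blood open. The blood list, fixed before the data were examined, had 3 of 7 measured genes higher and none lower (median 0.91, percentile 99.99). Neutrophil genes unseen when their list was written had a median of 4.40 over only 4 genes, so neutrophils may contribute; S100a8 and S100a9 had 257 and 760 reads, and 2 of the 13 listed genes had at least 20 reads after 6-OHDA alone. The labels name protein made in bacteria. Endotoxin-induced genes (7 of 17 also in a fixed list, 14 with at least 20 reads after 6-OHDA alone) had a median of 4.14. Bacterial components, colominic acid and a response to En2 itself cannot be told apart, since the labels list the protein and colominic acid for the En2 arm only.

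Many genes passed the rule of size in the captured pairs. Read depth alone is argued against: the punched pair, thinned to the reads of the En1+/- pair over 20 draws, gave 582 to 637 genes, on average 0.153 times the smaller captured count. The contralateral side against wild type, a pair without the genotype or the infused side, gave 2958 of 10742 measured genes. The En1+/- pair gave 3950 of 11500. The ratio of these counts was 0.749, between the bounds of 0.5 and 0.8 set in advance. The contralateral library held fewer reads than the En1+/- library (1908530 and 3272422 outside mitochondrial and ribosomal RNA genes). Few captured molecules and their amplification are therefore a candidate explanation that stays open. The contralateral side and wild type also differ in age and in treatment of the animals. For Engrailed dose, a ratio of at least 1.5 of opposite to same-direction genes, each relative to independent lists, was set in advance. Genes past the rule in both pairs gave 0.963 (interval over resampled genes 0.863 to 1.08), all under that bound. The interval also spans equal proportions of opposite and same-direction genes, the limit set for arguing against this explanation. These genes therefore do not decide whether opposite effects of Engrailed dose are the main source, and an effect on a part of them stays open.

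Microglia genes were higher on the infused side. Scaling is argued against, as the median of the microglia and macrophage list lay 0.73 above the upper end of the central 95% of random lists. A fall of dopaminergic transcripts relative to other genes is argued against too, as the dopaminergic list had a median of 0.34 (lower quartile 0.004). The pan-neuronal list went the other way (median -0.28, percentile 1.53). How many neurons were captured was not measured. More microglia in the captured tissue cannot be told apart from activated ones, since homeostatic genes (5 of 12 also in a fixed list) had a median of 0.26 over 11 genes that spread from a lower quartile of -0.23 to an upper quartile of 1.76. A response to En2, one to the cannula and one to any bacterial components in the infused preparation remain untested. Of the 17 endotoxin-induced genes only 3 were measured in this pair. All 3 were higher, and none of the list had 20 reads on the contralateral side.

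Around En1 on chromosome 1, 15 of 31 measured genes within 10 Mb passed the rule of size in En1+/- against wild type, a share of 48.4% where the median window held 34.8%. This share lay at percentile 99.2 of 1000 windows around random genes. Most such windows held more genes (median 97), and among 98 windows with a number of genes within 1.5 times it lay at percentile 95.9. Strain variants around the targeted allele may contribute, as a hypothesis. The windows overlap, and variants were not analysed here.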
